A study of Oryzias latipes with 6 samples.

How the data were processed

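Gene expression was measured in female medaka (Oryzias latipes) with 1-colour Agilent microarrays labelled with Cy3, per the labels. Wild-type fish were compared with fish in which olvl28m13 had been knocked out with CRISPR/Cas9, and all were kept under what the labels call LD conditions. Each of the 6 arrays carried a pool of ventral telencephalon, hypothalamus and pituitary from 3 fish, with 3 arrays and 9 fish per genotype, per the labels.

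The deposited table holds 1 raw intensity per probe and genotype on a linear scale and 1 normalized log2 value per probe and genotype, both made by the authors, so it has 4 value columns for the 6 arrays. The background correction, the software and the genome build are not given in the sources used here. The log2 ratio of the raw intensities minus the difference of the deposited log2 values was 0.0425 for all rows, with a largest deviation of 2.6e-06, which is how geometric means over the arrays of a genotype behave. The log2 values are centred per probe, and the baseline of that centring is not stated. Because the arrays of a genotype had been merged, no value per array was used, and no standard deviation, test or p-value could be computed. The planned tests had assumed values per array and were replaced by rules of size. The number of arrays limits the precision, and the spread between them is unknown here.

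The difference between genotypes was the deposited log2 value of the knockout minus that of the wild type. The table has 31150 rows, of which 60 are controls and 31090 are gene probes. Probes with a raw signal of at least 50 in at least 1 genotype were kept, which left 22409 probes (72.1%) of 15291 genes. This limit and the 2-fold limit for calling a probe different were set after the table had been looked at. Where a signal was at or below the higher of the dark-corner and negative-control signals (1.84 in wild type and 1.99 in the knockout), the difference was given as a bound against that level.

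Probes were named from the table and through a gene table of medaka assembly ASM223467v1, used only for names and for the order of neighbouring genes. Of the gene probes, 23565 matched it: 15806 by transcript accession, 4182 by gene number and 3577 by symbol, while 7525 did not. The table gave a symbol to 25927 probes, 12601 probes had only a numbered locus as a symbol and 5163 had none. Coordinates are those of the table, whose build is not named.

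For gene lists, 1 probe per gene was taken, the one with the highest mean signal. The median difference of each list with at least 5 measured genes was placed among the medians of 10000 random lists of the same size, matched on signal in 20 bins. A list was called outside when its median lay beyond the central 95% of random lists, where 5% lie by chance. Random draws treat genes as independent, whereas genes of 1 cell type or of 1 dissected part vary together between any sets of pools, so lists lie outside more often than that without an effect of genotype. The lists were fixed before the data were examined. Members matched by the gene name of a numbered locus were added later as an alternative, after some of their values had been seen.

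Named genes were the 12 with the largest positive and the 12 with the largest negative difference that had a gene symbol, 1 probe per gene, and of each list the 4 members with the largest absolute difference. The planned rule also asked for an adjusted p-value and for separated replicates, which this table cannot give. Some genes that the rule names are not reported here, although counts include them. The neighbourhood of the gene crhr2 was taken as 10 genes on each side. Chromosome bins of 1 Mb used 1 probe per locus of the table. A count with 1 probe per gene was made as an alternative after the values had been seen.

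In a check on lists of 14 genes drawn at random from the measured genes, 15 of 200 (7.5%) lay outside without an added shift. With a shift of 0.15 log2, 196 of 200 did. Lists drawn this way do not show how often genes that vary together lie outside. In the step on 15363 loci, 40 of 40 simulated bins with 6 added 2-fold loci were found, and 1 of 40 data sets without them was called. Alternatives covered the scaling between genotypes, the signal and fold limits, an added constant of 16, and the value taken per gene. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.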

Results

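The brain expression profile of medaka lacking olvl28m13 was compared with that of wild-type medaka. From what is known of the study, olvl28m13 is a long non-coding RNA that is induced by long days and lies close to crhr2, a receptor for corticotropin-releasing factor peptides. Each genotype was represented by 3 arrays, each hybridised with RNA pooled from the ventral telencephalon, hypothalamus and pituitary of 3 female fish. All signals and log2 values below are the authors' single values per genotype, so no replicate error can be given and no difference could be tested against the spread between arrays. The median raw signal of the kept probes was 420 in wild type and 433 in the knockout. The 7 spike-in rows past the signal limit had a median difference of -0.04 log2 and an SD over rows of 0.009. This SD describes how closely the spike-in rows match each other in merged values. It covers neither the spread between arrays nor that between pools.

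The targeted transcript was to be looked at first, as a check of the labels. No probe carried the name olvl28m13 (0 probes), so the genotype could not be checked on its own transcript. The probe with the largest negative difference of all was that of LOC105356286, an uncharacterized locus at position 30694923 to 30716195 of chromosome 17. Its raw signal was 106 in wild type and 1.59 in the knockout, which is at or below the negative-control level, and it was at least 54.8-fold lower in the knockout.

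The first comparison asked which transcripts differed between the genotypes. Both relaxin 3 genes, which encode a brain neuropeptide of the relaxin family, were higher in the knockout. The signal of rln3 was 304 in wild type and 1517 in the knockout (2.28 log2), and that of rln3a was 15.8 and 157 (3.27 log2). Among the genes lower in the knockout, gpr151, which encodes an orphan G protein-coupled receptor, had the largest difference of those with a gene symbol other than a locus number (-2.13), with signals of 176 and 41.4. The homeobox transcription factor genes pou4f2 and pou4f1 had differences of -2.05 and -1.78.

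Other genes higher in the knockout included the taste receptor gene tas1r2 (2.83), the extracellular matrix gene fbln1 (2.53) and nxpe3 (2.52). The plasma protein gene ambp (2.21), hhla1 (1.98), the magnesium transporter gene slc41a2 (1.96) and the ubiquitin ligase gene mib1 (1.95) were also higher. The folate transporter gene slc46a1 had a difference of 1.66 and the glycosyltransferase gene b4gat1 one of 1.60. Other genes lower in the knockout were tmem59 (-1.95), the mitochondrial apoo (-1.72), ccdc171 (-1.49) and tmem244 (-1.30). Netrin G2 (ntng2), a membrane-anchored axon guidance molecule, had a difference of -1.27, thrombospondin 2 (thbs2) one of -1.26, and lysmd1 one of -1.25. A probe named for the microRNA gene mir126 was at -1.15, but its locus in the table, 5046192 to 5055971 on chromosome 12, is longer than a microRNA, so the value need not be that of the microRNA. Second probes of apoo (0.11), slc41a2 (0.27) and slc46a1 (0.19) were not past 2-fold, while the second probe of pou4f1 was at -2.04. Several of these genes are dim: the wild-type signal of ambp was 15.5 and that of ntng2 was 50.8.

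In all, 261 of 22409 probes (1.16%) differed 2-fold or more, 158 higher and 103 lower in the knockout. The median difference was -0.01 log2, and the quartiles were -0.09 and 0.07. The share of probes past 2-fold was 1.79% at signals of 50 to 100 and 0.438% at signals over 10000. Of the 261 probes, 29.9% had no chromosome position, because they lay on unplaced sequence or had no locus given, against 18.3% of all kept probes. The count depends on the signal limit: without it, 602 probes differed 2-fold, and with the limit in both genotypes, 166 did.

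**Figure D1:**
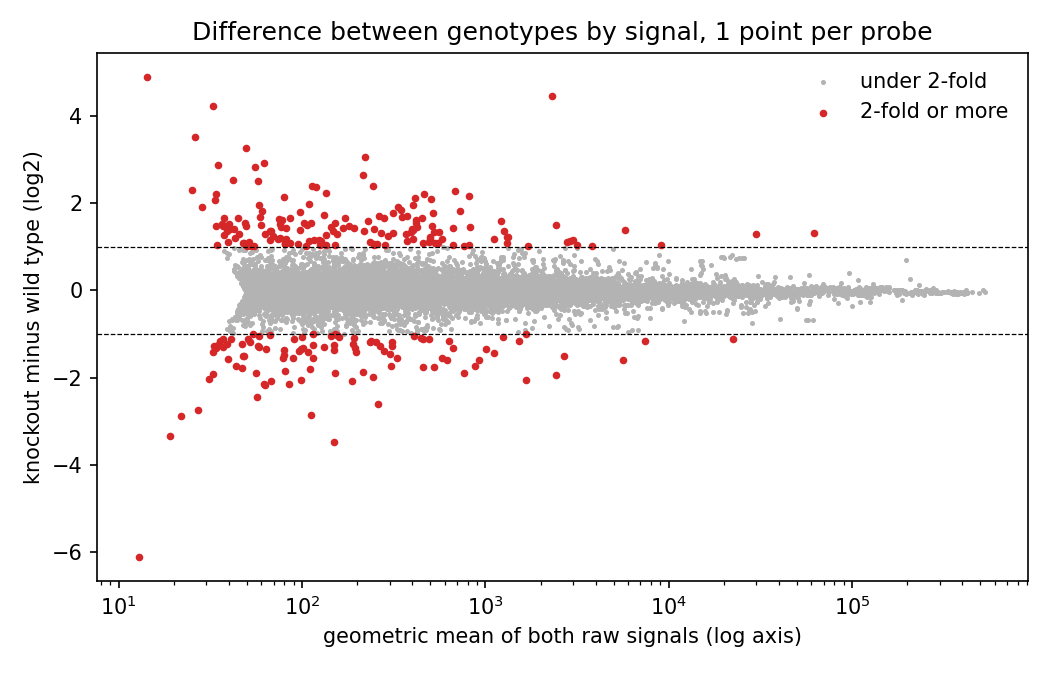
Knockout minus wild type (log2) against the geometric mean of both raw signals (log axis), 1 point per probe past the signal limit, with dashed lines at 2-fold. The 261 probes past 2-fold, 158 above and 103 below, spread over the signal range and thin out at high signals.

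The second comparison concerned crhr2 and its neighbours, because the targeted transcript lies near this gene. The probe of crhr2 itself (LOC101157488, chromosome 17, 29107055 to 29154150) had a signal of 81.9 in wild type and 187 in the knockout, a difference of 1.15. Of the 12 measured genes among crhr2 and 10 genes on each side, 5 differed 2-fold or more. Besides crhr2, the mitochondrial iron-sulfur protein gene iba57 (1.32) and mib1 (1.95) were higher, and ccdc13 (-1.11) was among those lower. The water channel gene aqp1 (0.10), thoc1 (-0.02) and usp14 (0.24) lay among them with small differences. None of the 10000 random lists of like signal held as many 2-fold genes (0 lists, with 3 the most in any). The median absolute difference was 0.54, against 0.04 to 0.17 in the central 95% of random lists. The separate list of crhr2 neighbours matched by symbol lay inside (14 genes, median -0.01), and some of its members, such as chn2 on chromosome 16 and ghrhr on chromosome 4, do not lie near crhr2 in the table. With a signal limit of 200, 2 neighbours differed.

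The 2-fold loci extended beyond these neighbours. From 28 Mb to the end of chromosome 17, 13 of 115 loci (11.3%) differed 2-fold or more, 8 higher and 5 lower in the knockout. On the rest of chromosome 17 the share was 0.751% and on the other chromosomes 0.830%. Loci higher there included LOC101158139, named outer dense fiber protein 2 (3.06), the cholesterol transporter gene npc1 (1.37) and LOC101159384, named as a receptor for pituitary adenylate cyclase-activating polypeptide (1.08). Loci lower there included the collectin-12-like gene LOC101162555 (-1.90), the chaperone gene calreticulin, LOC101169735 (-1.32), and the DNA replication gene mcm4 (-1.01). The start at 28 Mb was set after the values had been seen. Taken whole, chromosome 18 held a larger share of 2-fold loci (2.65%) than chromosome 17 (2.30%), and chromosome 2 held 2.17%. LOC105356286 and iba57 are not among the 13 loci of the region, because the locus of each was represented by a brighter probe. For iba57 that was a probe of jmjd4, at 0.11, and for LOC105356286 one of LOC101161835, at -0.17. For the same reason LOC101163523 (-1.85 and -1.79) and LOC105356284 (-1.34) are left out, as their loci were represented by probes at -0.01. LOC101161009 (-1.45) is left out because its own brighter probe was at -0.95.

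**Figure D2:**
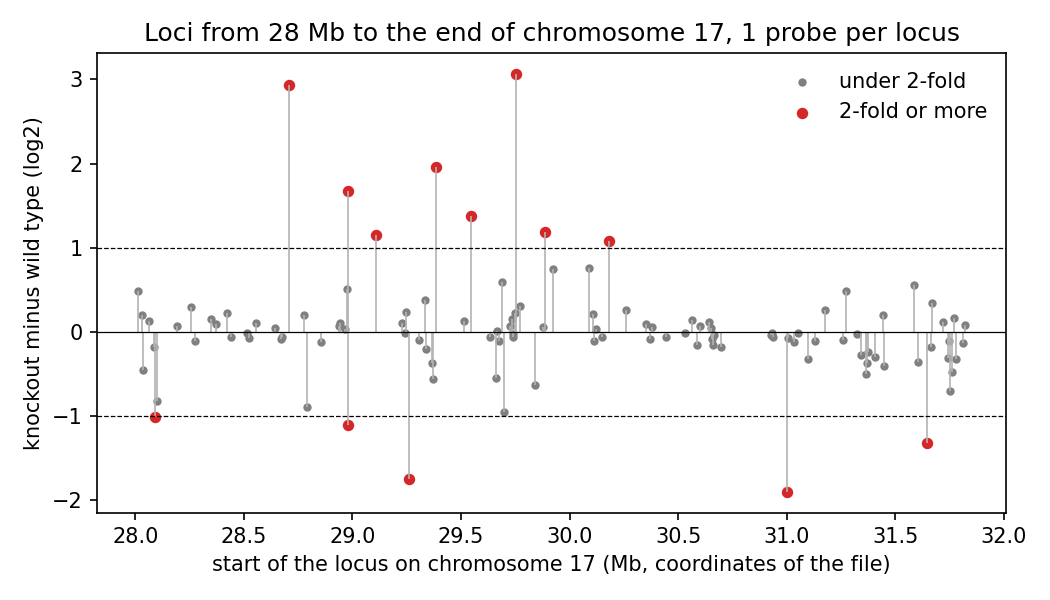
Knockout minus wild type (log2) against the start of each locus on chromosome 17 (Mb, coordinates of the table), 1 point per locus and its brightest probe, with dashed lines at 2-fold. The 13 loci past 2-fold, in red, lie between 28090660 and 31647941 and go both ways.

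The third comparison asked which gene groups differed. Interferon response and antigen presentation genes lay highest of the 26 lists matched by symbol, with a median of 0.32 and 13 of 13 measured members above 0. With members matched by gene name added, the median was 0.13, below those of 3 other lists, 24 of 28 members were above 0, and a class II histocompatibility gene, LOC101163710, was at -1.09; the list still lay outside. Its members included the antiviral genes rsad2 (1.19) and mx1 (0.87), the helicase gene dhx58 (0.85) and the transcription factor gene irf9 (0.61). Immediate early genes, which respond to neuronal activity, had a median of 0.14, with 14 of 20 members above 0. Among them, fosb was 2.14-fold higher in the knockout, ier2 was at 0.73 and npas4 at 0.57, while the brighter probe of fosl2 was at -0.51 and its second probe at -0.05.

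Pituitary hormone genes had a median of 0.09, with 9 of 12 members above 0. The somatotropin gene LOC101171460, which encodes growth hormone and was matched by gene name, was at 1.32, with signals of 38681 and 99370. The gene of the corticotropin precursor, pomc, was at 0.69, that of the follicle-stimulating hormone beta subunit, fshb, at 0.30, and that of the luteinizing hormone beta subunit, lhb, at -0.91. Stress axis genes had a median of 0.07 and included pomc and nr3c1 (0.50), a glucocorticoid receptor gene, while LOC100302444, also named glucocorticoid receptor and matched by gene name, was at -0.04 with signals of 7593 and 7622. The median of the hypothalamic neuropeptide list was 0.03. Of its 28 members, 2 were 2-fold higher, rln3 and rln3a, and 1 was 2-fold lower, the gene labelled oxt for oxytocin (-1.12), while LOC101160739, named isotocin-neurophysin, was at 0.09 and LOC101171147, named agouti-related protein, at 1.02, both matched by gene name, and gnrh3, a gonadotropin-releasing hormone gene, was at 0.69.

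The other lists outside on the high side were ribosomal proteins (median 0.02, 49 of 65 above 0), epithelium and skin (0.25, with the cell junction gene ppl at 1.37) and lens crystallins (0.15, 3 of 6 above 0, but -0.015 with the signal limit in both genotypes). On the low side lay myelin and oligodendrocyte genes (-0.14, 8 of 9 below 0), general neuronal genes (-0.10, with gap43 at -0.39), skeletal muscle (-0.12), connective tissue, cartilage and bone (-0.09, with the collagen gene col1a2 at -0.47) and cell cycle genes (-0.09). In all, 13 of the 26 lists lay outside, 8 above and 5 below. Most of these medians are small beside a 2-fold difference, and without the signal limit 7 lists lay outside.

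The photoperiod and thyroid list lay inside (-0.10), although dio1, which encodes a thyroid hormone deiodinase, was at 1.22 and its relative dio3 at -0.34. With members matched by gene name it lay outside (18 genes, -0.08). Medians of reproductive axis genes (-0.07), the circadian clock (-0.07, with per1 at -0.38), heat shock genes (-0.01), dopamine and serotonin genes (-0.08) and GABA and glutamate genes (-0.04) also lay inside. The same held for radial glia and astrocytes (-0.05), microglia and macrophages (0.05), erythrocytes (0.08), retina and pineal genes (-0.04), endothelium (0.06) and oxidative phosphorylation (-0.03). With members matched by gene name, radial glia and astrocytes (-0.12) and erythrocytes (0.11) lay outside.

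**Figure D3:**
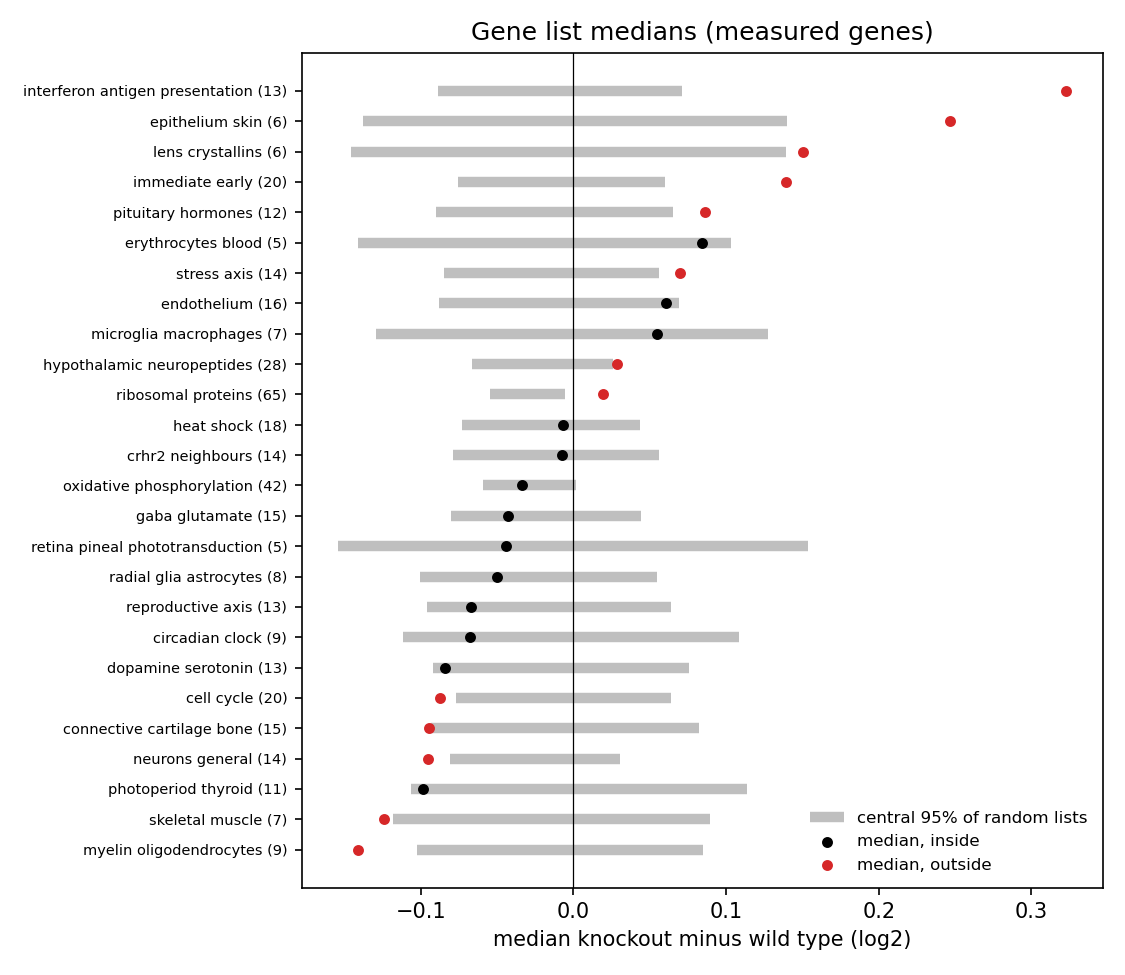
Median knockout minus wild type (log2) of each of the 26 gene lists, with the number of measured genes in parentheses and grey bars for the central 95% of 10000 random lists of like signal. Red points mark the 13 medians outside that range, of which the interferon and antigen presentation list at 0.32 lies highest.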

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

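The signal limits of 20 and 200, the 1.5-fold and 3-fold limits, the restriction to balanced probes, list members matched by gene name, and 1 probe per gene for chromosome 17 were chosen after seeing the data. Quantile, median and 75th percentile scaling of the 2 genotype profiles and an added constant of 16 left the counts of 2-fold probes, outside lists and 2-fold neighbours within 1.5 times. Without the signal filter, 602 probes differed 2-fold (312 higher, 290 lower) and 7 lists lay outside, since dim probes then enter. With the limit in both genotypes the counts were 166, 104 and 62, and with a limit of 200 they were 140, 87 and 53, with 6 lists outside and 2 neighbours past 2-fold, as fewer probes and lists were left. At 1.5-fold 796 probes differed (435 higher, 361 lower), and at 3-fold 86 did (52 higher, 34 lower), with 2 neighbours. Over the probes of a gene, the mean gave 171 genes with 61 lower, and the brightest probe also gave 61 lower. Of the 261 2-fold probes, 151 had centred values of opposite signs with a smaller size of at least 0.5 of the larger (102 higher, 49 lower). The median of the lens crystallin list turned from 0.15 to -0.015 with the signal limit in both genotypes. That limit leaves out crybb1 (0.38, wild-type signal 42.5), in a list with 3 members above 0 and 3 below. With list members matched by gene name, 16 lists lay outside, with photoperiod and thyroid, radial glia and erythrocytes added, and the interferon median was 0.13. At the end of chromosome 17, 18 loci differed with 1 probe per gene, against 13 with 1 probe per locus. Of 127 single named genes, 31 moved by over 0.1 log2 with 16 added to the signal. None reversed, but a constant added to both signals cannot turn the direction of a difference. The other settings moved none, but most of them could not. Signal limits leave the value of a probe unchanged, and median and 75th percentile centring shift all probes alike. No paired analysis was possible because the table holds 1 merged value per genotype. For the same reason the replicate block, leave-one-out, limma with its trend, robust and array weight options, the t-test, adjusted p-value thresholds, camera and fry were not run, and no alternative could be run for the targeted transcript, which had no probe. Differences of dim probes are the least certain, since they lie closest to background.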

Other observations

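Except for the tests on further habenula markers and on hindbrain genes, the tests in this part were chosen after the results had been seen. Gene families that recurred among the 2-fold probes were picked for the same reason. Of 5 probes for 4 NXPE family genes, 4 probes, of 3 genes, were 2-fold higher in the knockout and the remaining one was at -0.04. Of 6 probes for 3 low-density lipoprotein receptor-like genes, 5 probes were 2-fold higher, up to 2.16, of which 4 belong to 1 gene, LOC101156979. Of 5 probes for 4 cytochrome P450 3A genes, which encode enzymes of drug and steroid oxidation, 3 probes, of 2 genes, were 2-fold lower, down to -2.85, while cyp3a40 (0.49) and LOC101158047 (0.33) went the other way. Of 24 class I histocompatibility probes, 2 were 2-fold higher, and of 9 class II probes, 2 were 2-fold higher and 1 was 2-fold lower. Both of these families had a median of 0.08. Probes of close relatives can share sequence, so the probes of a family are not independent measurements. The uncharacterized LOC101164247 had a signal of 490 in wild type and 11006 in the knockout (4.45) with one probe, but 723 and 1263 (0.76) with its second probe, so the probes disagree.

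Genes that differed lay close together at the end of chromosome 17. Placement by chance was argued against: 6 of 10000 shuffles of the 2-fold differences among loci of like signal gave a 1 Mb bin as full as the fullest observed, which held 6 loci. With 1 probe per gene, a rule tried only after the locus rule had left out LOC105356286, that bin held 7 and 1 of 10000 shuffles matched it. Sequence differences under single probes may account for part of the pattern, since only 4 of the 16 changed genes had a second probe; for these the median ratio of the second difference to the first was 0.81. A chromosome segment that came with the edited locus and the loss of the transcript cannot be told apart, because knockout fish with such a segment would carry both. Whether the fish carry one was not measured. Of the 13 loci, 5 were lower. Whether LOC105356286 is the targeted transcript was not established.

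Of the genes lower in the knockout, 5 that are known from the habenula were picked because of their values (gpr151, pou4f1, ntng2, gng8 at -1.06 and kiss-1 at -0.96, which is not past 2-fold), so they show no shift of habenula genes as a group; both relaxin 3 genes were higher. A different amount of habenula in the dissected pools could lower these genes. The median of 7 further habenula markers was -0.06, inside the random range of -0.11 to 0.09 as set beforehand to count against it. Of these, 5 of 7 were below 0, from nrp1 at -0.29 and kctd12 at -0.17 to lef1 at 0.06. Among the 7, tac1 (0.03) and tac3 (-0.015) are also members of the hypothalamic neuropeptide list, so their values had entered an earlier comparison. A different amount of habenula was not excluded, because redrawing the 7 markers gave -0.17 to 0.03, beyond the random range. The wild-type signals of the 7 were 143 to 7607, against 50.8 to 176 for the 5 genes above. Markers that other dissected parts express as well would move little with the amount of habenula. Where they are expressed was not measured, so their median cannot decide the question. For more hindbrain in the knockout pools, 4 hindbrain genes likewise had a median of 0.06, inside -0.18 to 0.19. Of these, slc6a5 was at 0.004, gbx2 at -0.41 and none above 0.29, far below the relaxin 3 values. More hindbrain was not excluded either, because so few genes gave -0.41 to 0.29 when redrawn. Their expression in other parts was not measured. A difference carried by 1 or 2 arrays of a genotype stays open for the 5 habenula genes. Their median ratio of the smaller to the larger centred value was 0.10, which can be read only if the baseline of the table is known. The same holds for other genes with low ratios, such as rln3a (0.23), pou4f2 (0.14), nxpe3 (0.22) and LOC101164247 (0.13). The ratio of rln3 was 0.53, and the median over all 261 2-fold probes was 0.575.

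As a list, interferon and antigen presentation genes had a positive median difference. All 13 members matched by symbol were above 0, 4 of them past 1.5-fold. With members matched by gene name, 24 of 28 were above 0 and 4 below. More microglia or macrophages in the knockout pools stays open: the median of that list was 0.05, below the 0.10 to 0.85 of lists of its size drawn from the interferon list, but redrawing its own 7 members gave -0.07 to 0.26, and the interferon list with members matched by gene name gave 0.01 to 0.85. For the 4 interferon genes matched by symbol and past 1.5-fold, the median ratio of the smaller to the larger centred value was 0.10. A difference carried by 1 or 2 arrays may therefore underlie these, with the same condition on the baseline. Other ratios were higher. The second probe of rsad2 (1.46) had 0.59, against 0.24 for the first. Of members matched by gene name past 1.5-fold, LOC101156391 (2.15) had 0.29, LOC101170597 (1.83) 0.76, LOC101160459 (1.04) 0.94 and the lower LOC101163710 (-1.09) 0.66. An effect of genotype and a difference in infection or immune state between the tanks or pools were not tested.

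The centred values of a probe did not sum to 0, and a candidate explanation is a baseline set at the median of the 6 arrays. The spread of the mean of both centred values over the spread of their difference was 0.21. Simulation of that baseline gave 0.253 with a normal spread and 0.261 with a t spread of 5 degrees of freedom. A baseline at the mean of the 6 arrays gives 0, and one at the median of the wild-type arrays gave 0.64 with a normal spread. The observed value, 0.208 before rounding, lies within 0.05 of 0.253 but not of 0.261. It is also not within 0.05 of 0.27, the value named in the rule, which was itself set after the data had been looked at. The baseline was therefore left unsettled, as were the statements on single arrays that rest on it.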
